A study of Mus musculus with 16 samples.

How the data were processed

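Non-parenchymal cells of mouse liver were profiled by droplet single-cell RNA sequencing (10x, 5' chemistry) in 3 uninfected libraries, 3 libraries from 6 weeks after infection with Clonorchis sinensis and 2 from 16 weeks. Per the labels' protocols, livers were dissociated and the cells enriched by density and differential centrifugation. Per the submitters' processing notes, Cell Ranger 6.0.1 made the matrices, and the notes name the builds mm10 and GRCm38. The deposited matrices hold raw counts of UMIs per gene and cell barcode for 31053 genes, without normalization, 1 matrix per library. The 8 T cell receptor libraries of the series were not analysed here. Total depth per library ran from 34307931 to 84046949 UMIs.

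Barcodes were kept with at least 200 genes, at least 500 UMIs and at most 20% mitochondrial UMIs, which left 105812 of 112195. Doublets were scored from 1 simulated doublet per cell as the share of simulated doublets among 30 neighbours, and the top 0.8% per 1000 cells of each library were removed, 11917 in all. A first scoring, per library, had marked nearly all cells with cholangiocyte markers and most with stellate cell markers. It was replaced, after that was seen, by scoring in a space shared by all libraries.

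Counts were scaled to 10000 per cell and logged, and 2000 variable genes, 40 principal components, 20 neighbours and Leiden clustering at resolution 1 (leidenalg 0.10.2, igraph 0.11.9) gave the clusters, with no batch integration. Clusters of T or NK cells were clustered again on genes at least as high in T or NK cells as elsewhere, a restriction chosen after uninfected replicates 1 and 2 had split off from the other libraries. Clusters were named from marker genes written down beforehand, by the class with the highest mean fold over its markers, of which at least 3 were detected in at least 10% of cells and raised 2-fold over the other clusters. T or NK clusters also needed the first marker raised 1.5-fold and a raised marker that no other T or NK class shares. Thresholds that left clusters T0, T5, T7, T9, T12 and T14 unnamed were set after the clusters were seen. T0 and T14 had no raised marker of their own, T5 had no raised first marker and T12 had under 3 markers. T7 was shallow, with no marker among its top 10 genes, and T9 had Cd3e in over 50% of cells, which kept it out of ILC2. Their shares are reported beside those of the named classes, and since membership rests on the leading genes, those genes are given as a description of the cluster. CD8 T cells are clusters T3, T8 and T18, and CD4 T cells T1, T6, T11 and T13.

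UMIs were summed per library and class, so that libraries are the replicates, and a library with under 20 cells of a class was left out of that class. Cholangiocytes reached 20 cells in 1 library and were not tested for genes, so the lists written for them have no result. CD8 T cells, CD4 T cells, Kupffer cells, monocytes or macrophages, endothelial cells, and stellate cells or fibroblasts were tested with the quasi-likelihood test of edgeR 4.0.16 (TMM normalization, its default filter on low counts, prior count 2 for displayed log values), with group as the only term. The contrasts were 6 weeks minus uninfected, 16 weeks minus uninfected and 16 weeks minus 6 weeks. Adjusted p-values are Benjamini-Hochberg over the genes of a class and contrast, with a threshold of 0.05, and CPM of named genes use the TMM-scaled library sizes. Counts of cells per class and library were tested by the same edgeR method against total kept cells, adjusted over 25 classes or clusters. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated correlation, and with fry of the same package. All were adjusted over the lists of a class and contrast, and each list also had its members adjusted over the list alone.

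Genes named by value are, per class and contrast with uninfected, the 5 largest rises and 5 largest falls past the threshold whose groups did not overlap and whose mean CPM was at least 20, leaving out immunoglobulin and T cell receptor segments, numbered gene models, mitochondrial, ribosomal, haemoglobin and sex-linked genes and members of the lists of RNA from other cells. Added to these are up to 4 members past the threshold per list, genes fixed per class, and the top 3 in the contrast of 16 with 6 weeks. List members named where none passed over all genes, and Esm1 and Selp at 16 weeks, were chosen after their values were seen. Cells with a UMI of a gene were counted after thinning to 1000 UMIs, shallower cells left out, and compared by a two-sided exact permutation test. Gene positions come from the GRCm38.p6 annotation, matched by symbol, for 68 of 69 named genes.

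The classes, markers, gene lists, tests, rule for named genes and the main alternatives were chosen before the data were examined. The alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, the replicate number as a block, doublets kept, stricter cells (at least 500 genes and at most 10% mitochondrial UMIs), clustering at resolution 2, TMM across classes, a denominator without hepatocytes, erythroid cells, megakaryocytes or platelets and unnamed clusters, thinning to 2000 UMIs or none, and each library left out in turn. A set of 3 more was added after the data were seen: uninfected replicate 3 as the control alone, T9 counted as CD4 T cells, and CD8 T cells without T8. On counts simulated with the spread of the real libraries, edgeR recovered 79% to 88% of 4-fold changes in the classes other than stellate cells, where it recovered 65% at 6 weeks and 39% at 16 weeks. It recovered 3% to 58% of 2-fold changes. Of the simulated calls 4.08% to 12.2% were unchanged genes, over 5% in 10 of 12 comparisons, and camera called 2 of 30 unchanged lists in Kupffer cells and 0 in the other classes. Genes were simulated independently and lists drawn at random, so this cannot show how often camera miscalls lists of correlated genes. Of 4-fold changes in class shares, 68% were recovered. Other tools were R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.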

Results

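Single-cell RNA was sequenced from non-parenchymal cells of mouse liver, the cells other than hepatocytes, after infection with the liver fluke Clonorchis sinensis, a parasitic flatworm that lives in bile ducts. Uninfected livers gave 3 libraries, livers at 6 weeks of infection gave 3 and livers at 16 weeks gave 2. The 8 libraries held 112195 cell barcodes and 499164955 unique molecular identifiers (UMIs, each counting 1 captured RNA molecule), from 34307931 UMIs in 16-week replicate 2 to 84046949 in uninfected replicate 3. After filtering, 93895 cells were kept, with a median of 1952 UMIs per cell in 6-week replicate 2 and 4081.5 in 16-week replicate 1. The series title names tissue-resident memory CD8 T cells, chemokines and fibrosis, so the comparisons ask how the cell classes, and the genes of T cells, macrophages, endothelial cells and stellate cells, differed between infected and uninfected livers. Nothing in the labels states that the libraries of a group came from separate animals, so p-values measure the spread between libraries, which may be technical.

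At 6 weeks, a T cell cluster led by Il13 and Il1rl1, numbered T9, held 2.36% ± 1.17 (SD, n = 3) of all cells against 0.0356% ± 0.0111 (n = 3) in uninfected livers. Its share rose by 6.00 on the log2 scale (SE 0.74, adjusted p = 2.41e-10, edgeR). Il13 encodes a type 2 cytokine and Il1rl1 the receptor for the alarmin IL-33. In T9, 89.4% of 1011 cells had a UMI of the T cell gene Cd3e, 54.6% of Cd4, 40.8% of Il4 and 70.6% of Gata3, the transcription factor of type 2 lymphocytes. In B cells the shares were 3.00%, 0.421%, 0.494% and 0.262%. Group 2 innate lymphoid cells (ILC2), which also produce type 2 cytokines, rose from 0.0907% ± 0.0124 to 0.513% ± 0.158 (log2 2.48, SE 0.62, adjusted p = 0.00208). Monocytes or macrophages rose from 5.25% ± 1.40 to 13.9% ± 5.92 (log2 1.41, SE 0.56, adjusted p = 0.0413). Kupffer cells, the resident macrophages of the liver, fell in turn from 18.8% ± 8.78 to 6.01% ± 1.86 (log2 -1.64, SE 0.57, adjusted p = 0.0272). Megakaryocytes or platelets also fell (log2 -2.08, SE 0.63, adjusted p = 0.013). So did the T or NK clusters T0, T5 and T12, and cluster T7 rose, so that 9 classes or clusters passed. Cluster T5 was shallow, with a median of 1361 UMIs, 3.13% mitochondrial UMIs and Cd3e in 45.2% of cells. The T9 rise passed in all 13 alternative analyses and the ILC2 rise in 14 of 15. The Kupffer cell fall lost its call without uninfected replicate 2 (log2 -1.25, adjusted p = 0.142), 6-week replicate 2 (-1.64, 0.112) or 6-week replicate 3 (-1.44, 0.176), and its adjusted p ran from 0.00693 to 0.447 over 15 alternatives. At double resolution, and with the replicate number as a block, no share fell past the threshold. The megakaryocyte fall lost it without uninfected replicate 2 (-0.84), 6-week replicate 2 (-1.97) or 6-week replicate 3 (-1.97). The monocyte or macrophage rise lost its call when any library but 6-week replicate 1 was left out, with log2 changes from 1.11 without 6-week replicate 3 to 1.63 without uninfected replicate 2. The T7 rise lost its call without 6-week replicate 3 (1.36) or uninfected replicate 2 (1.49), and the T0 fall without 6-week replicate 2 (-1.75), 6-week replicate 3 (-1.29) or uninfected replicate 3 (-1.21). The T12 fall lost it without any library but uninfected replicate 3 (-1.18 to -1.502), and the T5 fall without any but 6-week replicate 1 or uninfected replicate 2 (-1.08 to -1.49).

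At 16 weeks, CD8 T cells made up 6.92% ± 1.49 (n = 2) of cells against 1.54% ± 1.03 (n = 3) in uninfected livers, a rise of 2.16 on the log2 scale (SE 0.63, adjusted p = 0.00496, edgeR). ILC2 stood at 0.504% ± 0.315 (log2 2.45, adjusted p = 0.00414) and T9 at 0.776% ± 0.440 (log2 4.41, SE 0.73, adjusted p = 8.93e-07). Neutrophils rose from 2.75% ± 1.27 to 9.26% ± 2.08 (log2 1.75, SE 0.62, adjusted p = 0.0247). Cluster T7, kept out of the CD8 T cells because its cells were shallow and its leading genes Lilrb4a and Nr4a3 were not markers of the class, rose from 0.135% ± 0.107 to 5.18% ± 0.608 (log2 5.25, SE 0.73, adjusted p = 1.21e-08). In T7, 31.5% of cells had a Cd8a UMI and 50.9% a Tnf UMI, against 0.523% and 4.68% of B cells. Tnf was also found in 43.8% of T0, 32.2% of T5 and 13.0% of T9 cells, and Cd8a in 2.02%, 1.97% and 0.692%. The median T7 cell had 965.5 UMIs and 4.36% mitochondrial UMIs, against 3305 and 1.17% in T9 and 3099 and 1.72% in B cells. Hepatocytes, which the isolation is meant to remove, fell from 9.01% ± 7.66 to 1.48% ± 1.10 (log2 -2.61, SE 0.76, adjusted p = 0.00496), and 6 classes or clusters passed in all. The CD8 T cell rise lost its call without 16-week replicate 1 (log2 1.93, adjusted p = 0.111; 0.000719 to 0.265 over 15 alternatives), and the T7 and T9 rises passed in all 13 alternatives. The ILC2 call was lost without 16-week replicate 2 (log2 1.62). The neutrophil call was lost without 16-week replicate 1 (1.503), 16-week replicate 2 (1.97) or uninfected replicate 1 (1.42). The hepatocyte call was lost without 16-week replicate 1 (-2.00) or uninfected replicate 1 (-1.86). At double resolution, 8 share calls of named classes were lost over all contrasts.

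Uninfected replicate 3 stood apart from the other uninfected libraries. B cells made up 22.8% of its cells against 6.65% and 3.79% in replicates 1 and 2, Kupffer cells 10.3% against 18.2% and 27.9%, and hepatocytes 1.07% against 16.4% and 9.61%. Its CD8 T cells were mostly naive-like: cluster T8, with Ccr7 among its leading genes, held 84.9% of them against 50.6% and 50.0%. With this library as the control alone, T9, T0 and hepatocytes passed at 6 weeks and T9 and T7 at 16 weeks. Hepatocytes rose at 6 weeks in that comparison (log2 4.12), and their log2 change at 16 weeks was 0.46, with no call.

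**Figure D1:**
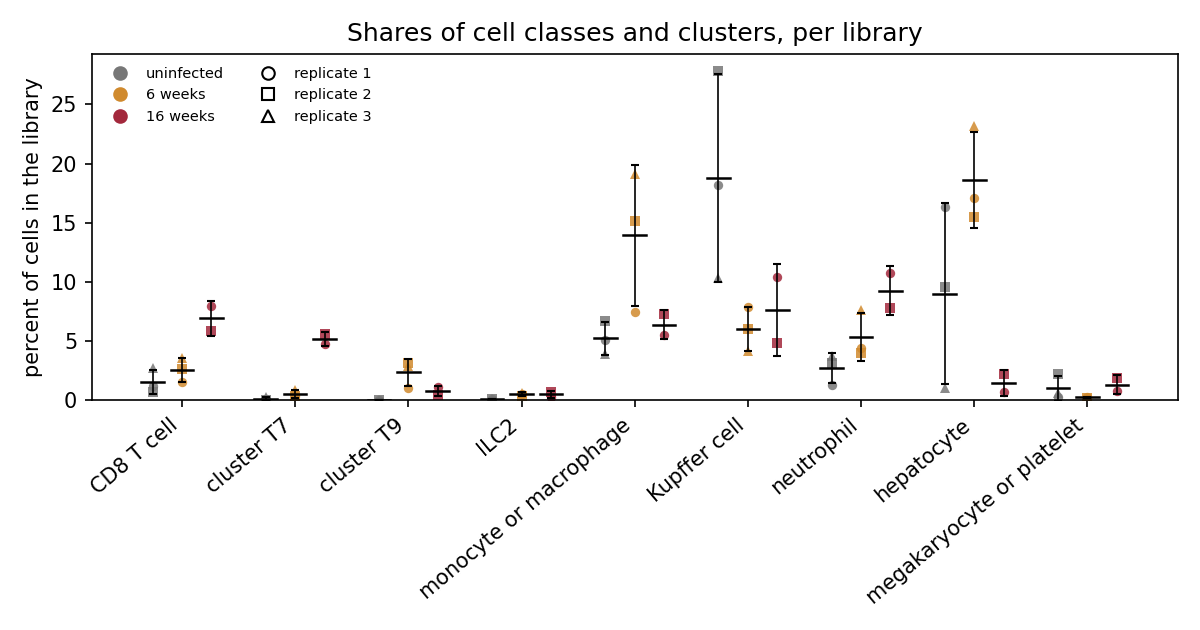
Percent of all kept cells in each library (y axis) for 9 classes or clusters (x axis), by group; points are libraries, lines are means and bars are SDs over 3, 3 and 2 libraries. CD8 T cells stood at 7.97% and 5.87% in the 16-week libraries and cluster T9 at 1.02% to 3.18% in the 6-week libraries.

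In CD8 T cells, the chemokine gene Xcl1 rose at 6 weeks from 74.9 ± 22.4 CPM (UMIs of the gene scaled to the same total in every library; SD, n = 3) to 352 ± 101 (n = 3). Its log2 fold change was 2.24 (SE 0.31, adjusted p = 0.0308, edgeR). The inflammatory cytokine gene Tnf rose from 105 ± 28.9 to 401 ± 72.8 (log2 1.92, SE 0.26, adjusted p = 0.0308), and these were the only genes of 8902 tested that passed. Ifng, the gene of interferon gamma, had a log2 fold change of 2.09 (SE 0.42, adjusted p = 0.126) and the chemokine gene Ccl4 of 2.00 (SE 0.40, adjusted p = 0.126). The tissue residency list, genes of T cells that stay in tissues, rose as a set (19 members, median log2 1.19, adjusted p = 4.19e-19, camera; adjusted p = 0.172 with an estimated correlation), with 1 member past the threshold and 8 when adjusted over the list alone. The cytotoxic effector list rose by a median of 0.43 (15 members, adjusted p = 0.000132; adjusted p = 0.172 with an estimated correlation), with 1 member past and 3 adjusted over the list alone. At this time 698 genes had an unadjusted p under 0.05, and DESeq2 called 57. The count was 46 without uninfected replicate 3, 15 without 16-week replicate 1, 14 without 16-week replicate 2, 6 without 6-week replicate 1, and 0 without 6-week replicate 2, 6-week replicate 3 or uninfected replicate 2. It was also 0 with doublets kept. Dissociation and stress genes rose too (median log2 0.49, adjusted p = 0.000238, camera; adjusted p = 0.582 with an estimated correlation), a call lost without uninfected replicate 1 (0.26), and the median was -0.19 against uninfected replicate 3 alone. Cluster T8 held 61.8% of CD8 T cells in uninfected livers and 43.0% at 6 weeks, and cluster T3, led by Cd8a, Gzmk and Ccl4, 33.4% and 52.8%.

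At 16 weeks, 124 of 8902 genes changed in CD8 T cells, 92 higher and 32 lower (DESeq2 190). Zfp683, which encodes the residency transcription factor Hobit and lies on chromosome 4 at 134051195 to 134058941 (GRCm38.p6), rose from 12.6 ± 3.06 CPM (SD, n = 3) to 85.3 ± 0.192 (n = 2). The log2 fold change was 2.80 (SE 0.38, adjusted p = 0.00625, edgeR). Prdm1, the gene of its relative Blimp-1, rose by 2.50 (SE 0.41, adjusted p = 0.0115), Rgs1 by 2.37 (SE 0.33, adjusted p = 0.00634), and Itga1, the CD49a chain of a collagen-binding integrin, by 2.22 (SE 0.49, adjusted p = 0.0473). With Xcl1, Bhlhe40 and P2rx7, 7 of 19 residency members rose and 15 when adjusted over the list alone, with none lower (median log2 1.98, adjusted p = 3.79e-19, camera; adjusted p = 0.111 with an estimated correlation). Cxcr6, the receptor for CXCL16 and a usual residency marker on chromosome 9 at 123806477 to 123811754, stood at 448 ± 9.38 CPM against 199 ± 100 (log2 1.21, SE 0.39, adjusted p = 0.163). Itgae, the gene of the CD103 integrin chain, had a log2 fold change of -0.19 (SE 0.74, adjusted p = 0.963) and Cd69 of 1.37 (SE 0.42, adjusted p = 0.146). Trat1, a T cell receptor adaptor gene, rose by 3.42 (SE 0.33, adjusted p = 0.000503) and passed in all 17 alternatives.

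Effector genes rose in CD8 T cells at 16 weeks in part. Tnf rose by 3.04 on the log2 scale (SE 0.28, adjusted p = 0.000503, edgeR) and Ifng by 3.30 (SE 0.45, adjusted p = 0.00625). Fasl, the gene of a death receptor ligand, rose by 2.45 (SE 0.30, adjusted p = 0.00443), and Ccl4 by 2.73 (SE 0.43, adjusted p = 0.0104). Of the cytotoxic effector list, 3 of 15 members rose, and 7 rose and 1 fell when adjusted over the list alone (median log2 0.39, adjusted p = 5.85e-08, camera; adjusted p = 0.0916 with an estimated correlation). The granzyme genes Gzmb (log2 1.60, SE 0.52, adjusted p = 0.166) and Gzmk (0.13, SE 0.51, adjusted p = 0.963) and the chemokine genes Ccl5 (0.57, SE 0.42, adjusted p = 0.621) and Ccl3 (1.69, SE 0.48, adjusted p = 0.104) did not pass. Of the inhibitory receptor list, Cd244 rose by 2.07 and Tox, a transcription factor of chronically stimulated T cells, fell by 1.11 on the log2 scale (SE 0.25, adjusted p = 0.0469). Pdcd1, the gene of PD-1, had a log2 fold change of 0.73 (SE 0.75, adjusted p = 0.741). Il4, a type 2 cytokine gene, stood at 173 ± 179 CPM against 1.29 ± 1.13 (adjusted p = 0.00694), and Cd40lg, usual in CD4 T cells, at 213 ± 162 against 14.6 ± 16.7 (adjusted p = 0.0115). In 16-week replicate 1, 281 of the 821 CD8 T cells had a UMI of Il4, Cd40lg or Ccr8, and 19.9% of those had a Cd4 UMI against 2.59% of the others. In 16-week replicate 2 it was 84 of 404, with a Cd4 UMI in 3.57% against 2.50%.

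Other measured differences went with this comparison. Cluster T8 held 61.8% of CD8 T cells in uninfected livers and 16.7% at 16 weeks, T3 33.4% and 64.6%, and T18, led by Cx3cr1, Klrg1 and S1pr5, 4.74% and 18.7%. Without T8, 34 genes changed in CD8 T cells, 10 higher and 24 lower, 15 of them among the 124. Genes of the dissociation and stress list rose by a median of 1.48 in CD8 T cells (13 of 19 adjusted over the list alone, adjusted p = 6.68e-11, camera; adjusted p = 0.281 with an estimated correlation), and the median was 0.15 without 16-week replicate 1. The Kupffer cell genes Clec4f (log2 -3.21, SE 0.64, adjusted p = 0.0308) and Slc40a1 (-3.27, SE 0.61, adjusted p = 0.0232) fell in CD8 T cells. The neutrophil gene S100a9 rose by 2.10, and Ighg1, an immunoglobulin gene of plasma cells, rose from 0.191 ± 0.331 to 16.3 ± 1.77 CPM (adjusted p = 0.00971). The count of changed genes was 24 without 16-week replicate 1, 199 without 16-week replicate 2, 66 without uninfected replicate 1 and 58 without uninfected replicate 2. Zfp683, Tnf, Fasl and Il4 passed in 16 of 17 alternatives, Ccl4 in 13 and Tox in 5.

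**Figure D2:**
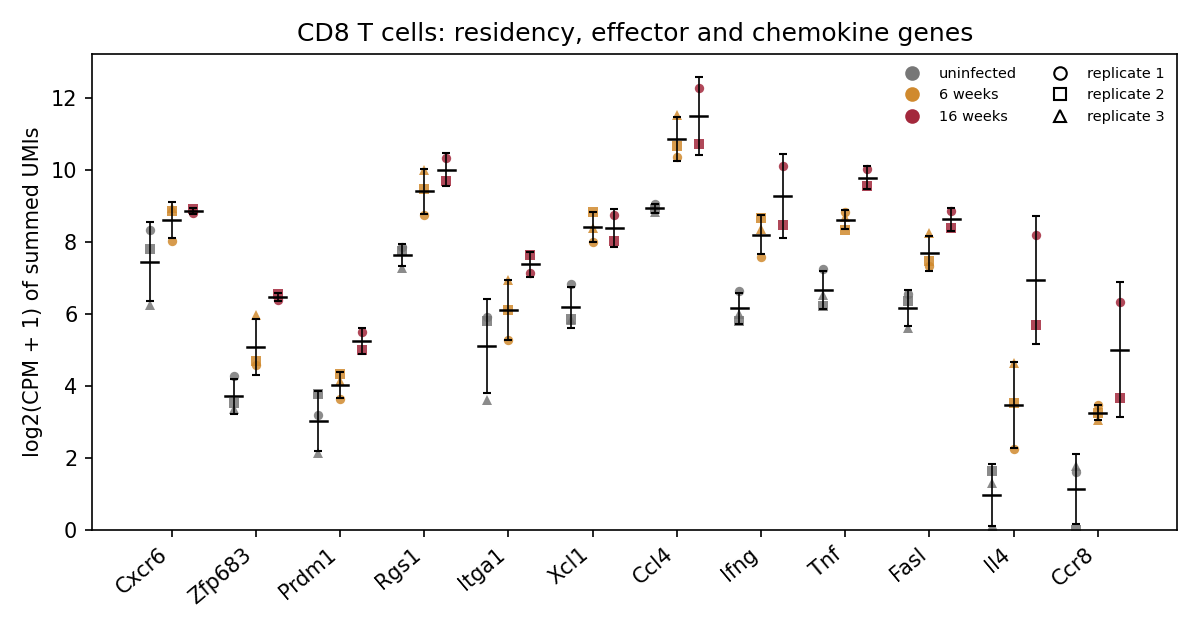
Expression of 12 genes in CD8 T cells as log2(CPM + 1) of UMIs summed per library (y axis), by group; points are libraries, lines are means and bars are SDs over 3, 3 and 2 libraries. On this scale, without TMM factors, Zfp683 averaged 87.8 CPM at 16 weeks against 12.6 in uninfected livers, and Cxcr6 461 against 205, a difference that did not pass the test.

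Cells were also scored for at least 1 UMI of a gene after thinning each cell to 1000 UMIs. Zfp683 was found in 0.958% ± 0.411 (SD, n = 3) of uninfected CD8 T cells, 2.88% ± 0.462 (n = 3) at 6 weeks and 10.3% ± 0.128 (n = 2) at 16 weeks. Each infected group against uninfected gave p = 0.1 in a two-sided exact permutation test. That is the smallest p that 3 libraries against 3 or 2 can give. In B cells, which should lack the gene, the shares were 0.216%, 0 and 0. Cxcr6 was found in 15.9% ± 10.2, 27.7% ± 10.2 and 34.7% ± 3.48 of CD8 T cells, exact permutation p = 0.3 at 6 weeks and 0.2 at 16 weeks, and in 0.404%, 0.347% and 0.366% of B cells. In B cells Ifng was found in 0.390%, 0.294% and 0.317%, Gzmb in 0.626%, 0.141% and 0.254%, and Itgae in 0.0212%, 0.0696% and 0.145%. For Ifng the CD8 T cell shares were 6.92% ± 0.525, 17.9% ± 4.80 and 31.2% ± 14.0 (exact permutation p = 0.1 at both times), and for Gzmb 10.8% ± 6.31, 13.7% ± 5.92 and 29.5% ± 0.769 (exact p = 0.6 and 0.1). Itgae stayed low at 0.821%, 2.39% and 1.53%. At 2000 UMIs Cxcr6 was found in 23.0%, 39.7% and 49.7%, and unthinned in 29.6%, 47.5% and 58.3%, with exact permutation p = 0.3 at 6 weeks and 0.1 at 16 weeks in both. Median depths lay between 2497.5 and 5395 UMIs in CD8 T cells and between 2210.5 and 4408 in B cells, and thinning left out 1 to 38 CD8 T cells per library.

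In CD4 T cells at 6 weeks, Furin, which encodes a protease, rose by 2.06 on the log2 scale (SE 0.27, adjusted p = 0.046, edgeR) and Nabp1 by 1.54 (SE 0.20, adjusted p = 0.046), the only genes of 9697 to pass. Il4 stood at 128 ± 45.4 CPM (SD, n = 3) against 17.1 ± 10.4 (log2 2.67, SE 0.40, adjusted p = 0.0812) and Gata3 at 94.9 ± 17.2 against 58.5 ± 14.6 (log2 0.67, SE 0.20, adjusted p = 0.316). The type 2 helper T cell list rose as a set (7 members, median log2 0.67, adjusted p = 1.09e-10, camera; adjusted p = 0.176 with an estimated correlation), with no member past the threshold and 5 adjusted over the list alone: Il4, Il1rl1, Ccr8, Gata3 and Ccr4. The tissue residency list rose by a median of 1.00 (adjusted p = 2.77e-13; adjusted p = 0.304 with an estimated correlation). An unadjusted p under 0.05 was found for 875 genes, and DESeq2 called 75. The count was 94 without uninfected replicate 3, 14 without 6-week replicate 1, and 0 without uninfected replicate 1, uninfected replicate 2, 6-week replicate 2, 16-week replicate 1 or 16-week replicate 2. It was also 0 with doublets kept and with stricter cells, and with T9 counted among CD4 T cells it was 264. Stress genes rose by a median of 0.61 (adjusted p = 3.42e-08, camera; adjusted p = 0.304 with an estimated correlation), with 0.10 and no call against uninfected replicate 3 alone. Cluster T1, naive-like and led by Igfbp4 and Ccr7, held 62.4% of CD4 T cells in uninfected livers and 42.5% at 6 weeks, and T6, led by Ccr8, 7.68% and 30.5%.

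At 16 weeks 37 genes changed in CD4 T cells, 34 higher and 3 lower (DESeq2 164, 104 higher and 60 lower). Xcl1 rose by 3.12 on the log2 scale (SE 0.50, adjusted p = 0.0382, edgeR), Ccl4 by 2.88 (SE 0.39, adjusted p = 0.0213), and Fasl by 2.82 (SE 0.50, adjusted p = 0.0468). Ifng rose by 2.59 (SE 0.42, adjusted p = 0.0382) and Il4 by 2.43 (SE 0.43, adjusted p = 0.0468). Ccr8, a chemokine receptor of type 2 and regulatory T cells, rose from 12.1 ± 6.02 to 127 ± 90.1 CPM (adjusted p = 0.0496). The tissue residency list rose by a median of 1.24, with 4 of 19 members past the threshold, among them Itga1, Rgs1 and Cd101, and 14 adjusted over the list alone (adjusted p = 4.05e-18, camera; adjusted p = 0.103 with an estimated correlation). The type 1 helper T cell list rose by 1.42, with 1 of 10 members past and 9 adjusted over the list alone (adjusted p = 8.69e-13; adjusted p = 0.103 with an estimated correlation). The type 2 helper T cell list rose by 0.92, with 2 of 7 past and 5 adjusted over the list alone (adjusted p = 7.65e-08; adjusted p = 0.103 with an estimated correlation). Foxp3, the regulatory T cell transcription factor, had a log2 fold change of -1.03 (SE 0.36, adjusted p = 0.268), and Lgmn fell by 1.83 on the log2 scale (SE 0.26, adjusted p = 0.0213). The count was 180 without uninfected replicate 3 (54 higher, 126 lower), 143 without 6-week replicate 3, 13 without 6-week replicate 2, and 0 without 16-week replicate 1, uninfected replicate 1 or uninfected replicate 2, so every one of these calls rested on each of those 3 libraries. It was also 0 with doublets kept, and 0 with uninfected replicate 3 as the control alone. T6 held 48.6% of CD4 T cells at 16 weeks and T1 24.7%, and stress genes rose by a median of 1.204 in the class (adjusted p = 3.83e-14, camera; adjusted p = 0.141 with an estimated correlation).

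In endothelial cells at 6 weeks, 20 of 12346 genes rose and 1 fell (DESeq2 285, 156 higher and 129 lower). Cd34, a marker of blood vessel endothelium that is low in sinusoids, on chromosome 1 at 194938821 to 194961292, rose from 13.7 ± 0.660 CPM (SD, n = 3) to 64.9 ± 26.4 (n = 3). The log2 fold change was 2.24 (SE 0.26, adjusted p = 0.0182, edgeR). Pi16 rose by 3.37 (SE 0.34, adjusted p = 0.0157), Selp, the gene of the leukocyte adhesion molecule P-selectin, by 2.52 (SE 0.35, adjusted p = 0.0382), and the collagen gene Col5a2 by 2.66 (SE 0.36, adjusted p = 0.0382). Cd36, Cd9, Il33 and Fbn1 also rose. The vascular and capillarised endothelium list rose as a set, with 3 of 16 members past the threshold and 8 adjusted over the list alone (median log2 1.01, adjusted p = 1.14e-15, camera), and held with an estimated correlation (adjusted p = 0.0267). The extracellular matrix and fibrosis list rose by a median of 0.85, with 2 of 23 members past and 8 adjusted over the list alone (adjusted p = 8.07e-11; adjusted p = 0.133 with an estimated correlation). The sinusoidal genes Stab2 (log2 -0.32, SE 0.17, adjusted p = 0.524) and Clec4g (-0.10, SE 0.24, adjusted p = 0.927) did not pass, and the sinusoidal identity list fell with a median log2 of -0.22 (adjusted p = 0.00222; adjusted p = 0.578 with an estimated correlation), a call lost without 6-week replicate 2 (-0.11) or uninfected replicate 3 (-0.13). Clusters B36 and B38, both with Vwf among their genes, held 1.41% and 1.31% of endothelial cells in uninfected livers and 5.38% and 4.07% at 6 weeks. The hepatocyte gene Mup20 also rose in endothelial cells, from 0.151 ± 0.110 to 8.93 ± 5.79 CPM (adjusted p = 0.0499). Stress genes rose by a median of 0.39 (adjusted p = 0.00494, camera; adjusted p = 0.655 with an estimated correlation), a call lost without uninfected replicate 1 (0.22) or 2 (0.13), and the median was -0.35 against uninfected replicate 3 alone. The count of genes was 0 without uninfected replicate 1, 1 without uninfected replicate 2, 288 without uninfected replicate 3 (70 higher, 218 lower), 7 without 6-week replicate 2, 6 without 6-week replicate 3, 13 without either 16-week library, and 0 against uninfected replicate 3 alone.

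At 16 weeks no gene passed in endothelial cells by edgeR, with 917 at an unadjusted p under 0.05 and 79 called by DESeq2. Cd34 had a log2 fold change of 1.17 (SE 0.29, adjusted p = 0.394), Selp of 2.03 (SE 0.37, adjusted p = 0.180) and Esm1, a gene of activated vessel endothelium, of 2.38 (SE 0.46, adjusted p = 0.224). The vascular and capillarised list rose at 16 weeks too, with 7 of 16 members adjusted over the list alone (median log2 1.06, adjusted p = 2.59e-13, camera; adjusted p = 0.0313 with an estimated correlation). The count was 221 without uninfected replicate 3, 6 without 6-week replicate 1, 5 without 16-week replicate 2 and 3 without 16-week replicate 1.

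**Figure D3:**
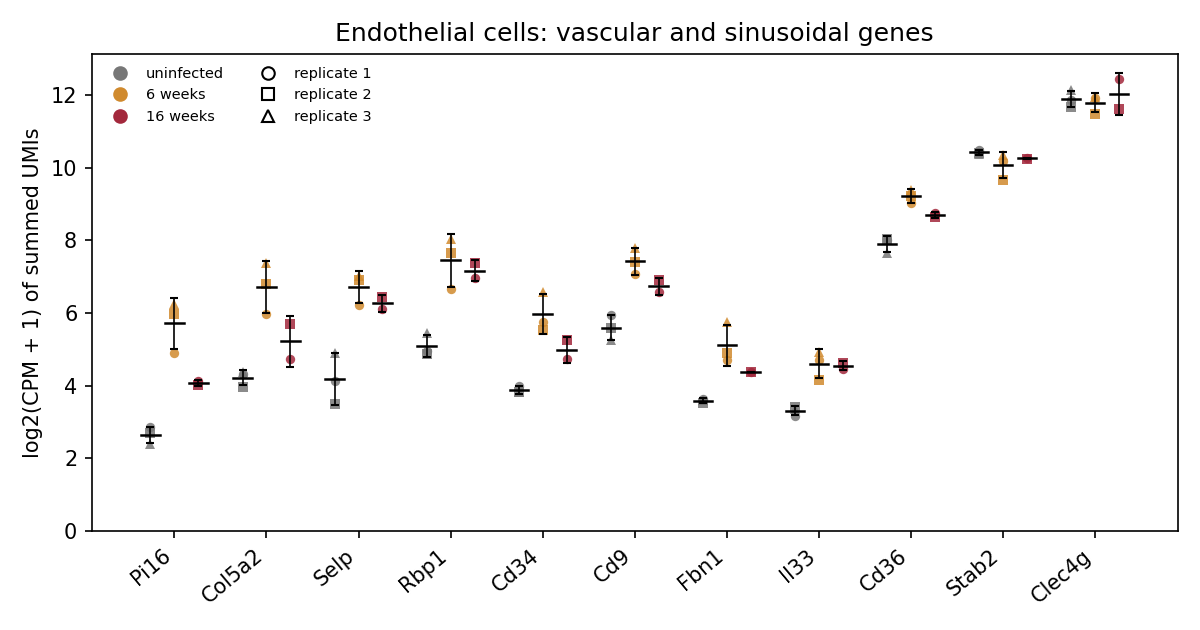
Expression of 11 genes in endothelial cells as log2(CPM + 1) of UMIs summed per library (y axis), by group; points are libraries, lines are means and bars are SDs over 3, 3 and 2 libraries. On this scale, without TMM factors, Cd34 averaged 13.8, 64.8 and 31.2 CPM in uninfected, 6-week and 16-week livers, while the sinusoidal gene Clec4g did not pass the test at either time.

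In Kupffer cells no gene passed at 6 or 16 weeks by edgeR, with 2617 and 916 genes at an unadjusted p under 0.05 and 428 and 28 called by DESeq2. The scar-associated macrophage list, lipid-handling and matrix genes of macrophages in fibrotic liver, rose as a set at 6 weeks (15 members, median log2 1.43, adjusted p = 5.18e-12, camera; adjusted p = 0.145 with an estimated correlation). No member passed the threshold over all genes, and 10 did when adjusted over the list alone. Among these, Trem2, a lipid receptor gene, stood at 178 ± 62.7 CPM (SD, n = 3) against 59.7 ± 21.8 (log2 1.57, SE 0.34, adjusted p = 0.166). Cd63 had a log2 fold change of 3.13 (SE 0.42, adjusted p = 0.166) and Cd9 of 2.62 (SE 0.40, adjusted p = 0.166). At 16 weeks the list rose by a median of 0.80, with 5 members adjusted over the list alone (adjusted p = 7.46e-08; adjusted p = 0.112 with an estimated correlation). Proliferation genes rose by a median of 0.96 at 6 weeks (adjusted p = 2.91e-05; adjusted p = 0.721 with an estimated correlation) and fell by 0.69 at 16 weeks (adjusted p = 0.0290; adjusted p = 0.697 with an estimated correlation). The 16-week call was lost without uninfected replicate 2 (-0.13) or 3 (-0.89) and reversed without 16-week replicate 1 (0.51). The cycling cluster B30 held 4.11%, 12.5% and 3.51% of the class. The alternative activation list rose by 0.49 (adjusted p = 0.0277; adjusted p = 0.561 with an estimated correlation), a call lost without 6-week replicate 2 (0.22) or uninfected replicate 3 (0.84). Without uninfected replicate 3 edgeR called 1925 genes at 6 weeks, 1001 higher and 924 lower, and without 6-week replicate 1 it called 11. Cluster B9 held 34.6% of Kupffer cells in uninfected livers (52.2%, 39.4% and 12.1% in replicates 1, 2 and 3), 10.8% at 6 weeks and 14.7% at 16 weeks.

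In monocytes or macrophages no gene passed at 6 or 16 weeks by edgeR, with 911 and 749 at an unadjusted p under 0.05 and 39 and 13 by DESeq2. Retnla, a gene of alternatively activated macrophages on chromosome 16 at 48842609 to 48844461, stood at 111 ± 66.8 CPM (SD, n = 3) at 6 weeks against 0.128 ± 0.128 (n = 3), adjusted p = 0.383. The eosinophil attractant gene Ccl24 stood at 341 ± 107 against 153 ± 47.2 (log2 1.15, SE 0.28, adjusted p = 0.474). The alternative activation list rose at 6 weeks (13 members, median log2 0.43, adjusted p = 0.00029, camera; adjusted p = 0.247 with an estimated correlation), with 3 members adjusted over the list alone: Retnla, Ccl24 and Mgl2. The Kupffer identity list fell with a median log2 of -0.99 at 6 weeks, with 8 of 15 members lower when adjusted over the list alone, and held with an estimated correlation (adjusted p = 1.22e-13, camera; adjusted p = 0.0393 with an estimated correlation). Kupffer genes were also lower in whole libraries, Clec4f at 1213, 1380 and 903 CPM in uninfected livers and 552, 233 and 177 at 6 weeks. Stress genes rose at 6 weeks by a median of 0.57 (adjusted p = 0.00029; adjusted p = 0.539 with an estimated correlation), with -0.16 against uninfected replicate 3 alone. The scar-associated list fell at 16 weeks (-0.73, adjusted p = 0.00394; adjusted p = 0.493 with an estimated correlation). That call was lost without 16-week replicate 1 (-0.61) or uninfected replicate 1 (-0.05), and against uninfected replicate 3 alone the list rose (0.65). Spp1 had a log2 fold change of -1.24 (SE 1.19, adjusted p = 0.794) and Il1b of 1.10 (SE 0.55, adjusted p = 0.63). Without uninfected replicate 3, 4 genes passed at 6 weeks and 178 at 16 weeks, without 16-week replicate 1, 1 passed at 6 weeks, and without 16-week replicate 2, 1 and 2 passed. Cluster B19 held 8.34%, 24.7% and 12.0% of the class.

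In stellate cells or fibroblasts, the matrix-producing cells of the liver, no gene of 5848 passed at 6 or 16 weeks by edgeR, with 529 and 351 at an unadjusted p under 0.05 and 7 and 5 called by DESeq2. The class was thin, with 23 to 105 cells per library. The 105 cells of 6-week replicate 2 had a median of 719 UMIs, against 3821 to 7084 in the other libraries. At double resolution a class named mesothelial by its markers held 15, 11 and 33 cells in uninfected replicates 1 to 3. It held 8, 15 and 11 at 6 weeks and 13 and 14 at 16 weeks. The stellate class then held 45, 95 and 10 cells, 22, 70 and 15, and 10 and 10. The tested class may therefore mix both cell types, in parts that differ between libraries. Timp1, an inhibitor of matrix-degrading proteases, stood at 717 ± 318 CPM (SD, n = 3) at 6 weeks against 79.8 ± 27.5 (log2 3.19, SE 0.42, adjusted p = 0.0941). It stood at 285 ± 66.8 (n = 2) at 16 weeks (log2 1.86, SE 0.45, adjusted p = 0.798). The extracellular matrix and fibrosis list rose at 6 weeks, with no member past over all genes and 11 of 27 adjusted over the list alone (median log2 0.90, adjusted p = 4.79e-15, camera; adjusted p = 0.365 with an estimated correlation). Among these were Timp1, Col4a1 (log2 1.38, SE 0.28), Fn1 (1.22, SE 0.39) and Lox (1.30, SE 0.46). The fibrillar collagen genes Col1a1 (log2 1.24, SE 1.00, adjusted p = 0.717) and Col3a1 (1.06, SE 0.71, adjusted p = 0.662) did not pass. At 16 weeks the list's median was -0.58 (adjusted p = 0.0663), and the myofibroblast contraction list fell with a median log2 of -1.81 (adjusted p = 0.000269; adjusted p = 0.74 with an estimated correlation), a call lost without uninfected replicate 3 (-0.61). The stellate cell quiescence list did not pass at either time (medians -0.80 and -0.92).

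Chemokine ligands named in the series title were read by class, as mean CPM over the libraries with at least 20 cells. Ccl5 was highest in NK cells or ILC1 (14455) and next in CD8 T cells (7581), though in uninfected livers gamma-delta T cells stood above CD8 T cells (8504 against 7134). Xcl1 was highest in NK cells or ILC1 (1661). Over all libraries Ccl3 and Ccl4 stood at 3763 and 5442 in basophils or mast cells and 2372 and 4249 in neutrophils, but in uninfected livers neutrophils were the higher (2982 against 2885 and 4863 against 4236). Cxcl16, the ligand of Cxcr6, stood at 315, 295 and 266 in endothelial cells, monocytes or macrophages and Kupffer cells. Its log2 fold change at 6 weeks was 0.62 in Kupffer cells (SE 0.24, adjusted p = 0.186, edgeR) and -0.26 in endothelial cells (SE 0.14, adjusted p = 0.531). Cxcl12 was highest in stellate cells or fibroblasts (968) and Ccl24 in Kupffer cells (1095). Cxcl9, induced by interferon gamma, had no single leading class, with 140 in monocytes or macrophages, 116 in conventional dendritic cells and 112 in megakaryocytes or platelets. As a set, chemokine ligands did not pass in CD8 T cells at 6 weeks (median log2 -0.56, adjusted p = 0.597, camera) or 16 weeks (-0.53, adjusted p = 0.295). The camera direction was up there, against the sign of the median, with Ccl4 and Xcl1 as the called members at 16 weeks. The set rose in Kupffer cells at 6 weeks (0.65, adjusted p = 0.0179; adjusted p = 0.721 with an estimated correlation), a call lost without 6-week replicate 2 (0.18). It also rose there at 16 weeks (0.49, adjusted p = 0.000989; adjusted p = 0.296 with an estimated correlation), a call lost without 16-week replicate 1 (-0.09).

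The lists tested over the 6 classes gave 82 tests per contrast. At 6 weeks 40 passed, 29 up and 11 down, and 2 with an estimated correlation. At 16 weeks 47 passed, 30 up and 17 down, and 1 with an estimated correlation. By fry, 1 list passed at 6 weeks, 2 at 16 weeks and 0 between the times. RNA of other cell types moved with the groups. Hepatocyte RNA rose at 6 weeks in all 6 classes (medians 0.46 in Kupffer cells to 1.85 in CD8 T cells). It fell at 16 weeks in all but stellate cells (-0.95 in endothelial cells to -1.93 in Kupffer cells), and neither direction held with an estimated correlation (lowest adjusted p 0.200). The 6-week hepatocyte RNA call was lost without 6-week replicate 2 in Kupffer cells (0.025), endothelial cells (0.15) and stellate cells (0.35), and without uninfected replicate 3 in Kupffer cells (0.096) and endothelial cells (0.61). The 16-week call was lost without uninfected replicate 1 in CD8 T cells (0.026) and endothelial cells (-0.33), and without 16-week replicate 1 in endothelial cells (-0.25). Against uninfected replicate 3 alone, hepatocyte RNA rose at 16 weeks in endothelial cells (0.82), and had no call in CD8 T cells (0.39), CD4 T cells (-0.29), Kupffer cells (0.052) or monocytes or macrophages (-0.030). Neutrophil RNA rose at 16 weeks in CD8 T, CD4 T, Kupffer, monocyte or macrophage and endothelial cells (medians 1.96 to 2.40; adjusted p = 0.103 to 0.325 with an estimated correlation). So did plasma cell RNA (0.45 to 2.05; adjusted p = 0.103 to 0.395 with an estimated correlation), a call lost without uninfected replicate 3 in Kupffer cells (0.64) and endothelial cells (0.89). Dissociation and stress genes rose at 16 weeks in all 6 classes (0.65 to 1.62; adjusted p = 0.141 to 0.74 with an estimated correlation). The stress median without 16-week replicate 1 was -0.26 in Kupffer cells, -0.01 in endothelial cells and 0.01 in monocytes or macrophages, with the calls lost, as was the call in stellate cells without 16-week replicate 2 (0.038). The heat shock gene Hspa1a stood at 1041 CPM in the whole of 16-week replicate 1. It stood at 88.6 and 76.6 in uninfected replicates 1 and 2 and at 181 to 228 in the remaining libraries. The stress gene Fos also stood lower in uninfected replicates 1 and 2 (211 and 281) than in all other libraries (594 to 1552).

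Interferon response genes fell at 6 and 16 weeks in CD8 T cells (medians -0.33 and -0.33; adjusted p = 0.582 and 0.584 with an estimated correlation). They also fell in CD4 T cells (-0.27 and -0.45; adjusted p = 0.423 and 0.248 with an estimated correlation) and in monocytes or macrophages (-0.29 and -0.64; adjusted p = 0.539 and 0.318 with an estimated correlation). In CD8 T cells the 6-week call was lost without uninfected replicate 1 (-0.01), and the 16-week call without 16-week replicate 1 (-0.01) or uninfected replicate 1 (-0.11). In CD4 T cells the 6-week call was lost without uninfected replicate 1 (-0.07), and in monocytes or macrophages without 6-week replicate 3 (-0.17). Against uninfected replicate 3 alone, no interferon call held in CD8 T cells (0.13 and -0.04) or CD4 T cells (0.09 and -0.10), and in monocytes or macrophages it held at 16 weeks (-0.13) but not at 6 weeks (0.42). In endothelial cells interferon genes rose at 6 weeks (0.26, adjusted p = 0.0146; adjusted p = 0.768 with an estimated correlation) and fell at 16 weeks (-0.18, adjusted p = 0.0156; adjusted p = 0.663 with an estimated correlation). The 6-week call was lost without 6-week replicate 2 (-0.12) or uninfected replicate 1 (0.20) or 3 (0.22), and the 16-week call without 16-week replicate 1 (-0.04) or uninfected replicate 2 (-0.05) or 3 (-0.20). MHC class II genes fell in endothelial cells (-1.44 and -1.37; adjusted p = 0.578 and 0.517 with an estimated correlation), with medians of 0.70 and 0.69 against uninfected replicate 3 alone, and the 16-week call was lost without uninfected replicate 2 (-0.71) or 16-week replicate 1 (-0.78). In Kupffer cells they rose at 16 weeks (0.49, adjusted p = 0.00547; adjusted p = 0.443 with an estimated correlation), a call lost without 16-week replicate 2 (0.31) or uninfected replicate 3 (0.43). Inflammatory cytokine genes rose in Kupffer cells at 16 weeks (1.09, adjusted p = 1.35e-05; adjusted p = 0.293 with an estimated correlation), a call lost without 16-week replicate 1 (-0.22). They rose in monocytes or macrophages too (0.53 at 6 weeks and 0.98 at 16 weeks; adjusted p = 0.374 and 0.318 with an estimated correlation), calls lost without uninfected replicate 1 (0.32) and 16-week replicate 1 (0.03). The TGF-beta and PDGF signalling list rose in monocytes or macrophages at 6 weeks (0.33, adjusted p = 0.00214; adjusted p = 0.374 with an estimated correlation), a call lost without 6-week replicate 3 (0.12) or uninfected replicate 2 (0.28), and passed in no other class. The circulating and naive T cell list did not pass in CD8 T cells (medians -0.32 and -0.54), nor did inhibitory receptors (0.54 and 0.73) or chemokine receptors (0.24 and 0.31). The regulatory T cell list fell in CD4 T cells at 16 weeks (-0.27, adjusted p = 0.0162; adjusted p = 0.269 with an estimated correlation), a call lost without 16-week replicate 2 (-0.20) or uninfected replicate 1 (-0.22). Erythroid RNA fell at 6 weeks in CD8 T cells (-2.22, adjusted p = 0.0338; adjusted p = 0.582 with an estimated correlation), a call lost without uninfected replicate 3 (0.79), 6-week replicate 1 (-2.06) or 6-week replicate 3 (-1.88).

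Directly between the infected groups, hepatocytes fell from 18.6% ± 4.07 (SD, n = 3) of cells at 6 weeks to 1.48% ± 1.10 (n = 2) at 16 weeks (log2 -3.66, SE 0.80, adjusted p = 0.000249, edgeR). Cluster T7 rose by 3.28 on the log2 scale (SE 0.67, adjusted p = 0.000144) and megakaryocytes or platelets by 2.44 (SE 0.68, adjusted p = 0.00519). The hepatocyte call was lost without 16-week replicate 1 (-3.04) and the megakaryocyte call without 16-week replicate 2 (1.69). At double resolution neither of these calls held. CD8 T cells had a log2 change of 1.42 (SE 0.62, adjusted p = 0.0764). Within CD8 T cells Klrb1f, a receptor gene of the NK gene complex, rose by 3.31 (SE 0.38, adjusted p = 0.0102), and Trav7-4, a T cell receptor segment, by 2.19 (SE 0.28, adjusted p = 0.0123). Within CD4 T cells Cd160 rose by 2.19 (SE 0.29, adjusted p = 0.042), and the immunoglobulin segment Igkv14-111 rose from 0.413 ± 0.365 to 20.6 ± 6.42 CPM (adjusted p = 0.042). These 4 genes were named after their values were seen. No gene passed in the other 4 classes by edgeR, with 497 to 1213 at an unadjusted p under 0.05 and 13 to 80 called by DESeq2. Matrix genes of stellate cells fell with a median log2 of -1.48 (adjusted p = 2.38e-19, camera; adjusted p = 0.118 with an estimated correlation), with 9 of 27 lower when adjusted over the list alone. The CD8 T cell count was 0 without 6-week replicate 2, 51 without uninfected replicate 3, 38 without 16-week replicate 2, 27 without uninfected replicate 1 and 6 without 16-week replicate 1. The CD4 T cell count was 30 without uninfected replicate 3, 10 without uninfected replicate 1, 8 without 6-week replicate 3, 1 without 16-week replicate 1, and 0 without 16-week replicate 2, 6-week replicate 1, 6-week replicate 2 or uninfected replicate 2. It was also 0 with doublets kept and with stricter cells.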

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

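Of the tests here, those of cluster T8, of dissociation, of a wrong label and of the splits were chosen only after the results were seen, and those of free RNA, CD4 T cells and preparation before. Between 16 and 6 weeks, 4 genes and 3 shares differed by test. No label ties an uninfected library to either time, so length of infection cannot be told apart there from age or preparation. In CD8 T cells Klrb1f was higher at 16 weeks by 3.31 on the log2 scale and Trav7-4 by 2.19. In CD4 T cells Cd160 was higher by 2.19 and Igkv14-111 by 5.51, the latter at 0.413 CPM at 6 weeks and 20.6 at 16 weeks. The share of hepatocytes differed by -3.66, that of megakaryocytes or platelets by 2.44 and that of cluster T7 by 3.28. No cause was tested for these 7.

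In CD8 T cells at 16 weeks, 7 of 19 residency and 3 of 15 effector genes passed, all higher, and 1 effector gene was lower when adjusted over the list alone. The list calls did not hold with an estimated correlation (camera, adjusted p = 0.111 and 0.0916). The labels' biological difference, 16 weeks of infection, remains untested as the reason. Without T8 the residency median was 1.01 against 1.98 in all cells, so a smaller rise remained. Its mean score difference was 0.91 (SE 0.43), from only 3 and 2 libraries. T3 also went from 33.4% to 64.6% of CD8 T cells and T18 from 4.74% to 18.7%. Leaving out T8 therefore cannot decide whether the mix of cells accounts for the residency genes. For the cytotoxic effector list the median without T8 was 0.10, which leaves a loss of naive cells open there too. Free RNA of other cells is argued against, since the 10 called members were in the median 94.3-fold and 97.2-fold higher in CD8 T cells than in the lowest of 3 other classes. A response to dissociation stays open: without 16-week replicate 1 the residency median was 1.06 while that of stress genes went from 1.48 to 0.15, but 1 library alone can exclude nothing.

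Il4, Cd40lg and Ccr8 in CD8 T cells at 16 weeks may come in part from CD4 T cells in the CD8 clusters. In 16-week replicate 1, cells with a UMI of any of these genes had Cd8a or Cd8b1 in 67.6% against 90.9% of the other cells, a difference of -23.3 points, and a Cd4 UMI in 19.9% against 2.59%. In 16-week replicate 2 the shares with Cd8a or Cd8b1 were 92.9% and 89.7%, a difference of 3.17 points, and those with a Cd4 UMI 3.57% and 2.50%. The libraries thus differ, and the question stays open.

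In Kupffer cells edgeR called 1925 genes at 6 weeks without uninfected replicate 3 and 0 with all libraries (2617 at an unadjusted p under 0.05), where DESeq2 called 428 and edgeR with no filter on low counts 890. Without 6-week replicate 1 edgeR called 11. A wrong label is argued against, since T9 made up 0.0484% of that library and at least 0.465% of every infected one. On an axis over these genes with uninfected replicates 1 and 2 at 0 and the 6-week libraries at 1, uninfected replicate 3 lay at 0.668 and the 16-week libraries at 0.678 and 0.687. These genes were picked by leaving uninfected replicate 3 out, and infection alone would also move the 16-week libraries along the axis. The position therefore decides nothing, and whether uninfected replicates 1 and 2 differ from all other libraries in preparation stays open. A difference between animals was not tested.

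The 6 libraries of the 6-week comparison can be split in 10 ways, too few for a share under 0.05. Counted with the real split itself, 2 splits reached the real count in CD8 T cells (real 2 genes, highest other 9). In CD4 T cells 2 splits did so (2, highest other 10). All 10 did in Kupffer cells (0, highest other 0), monocytes or macrophages (0, highest other 0) and stellate cells or fibroblasts (0, highest other 1). Every split reaches a real count of 0, so these classes decide nothing. For endothelial cells (21, highest other 0) and class shares (9, highest other 0) only the real split reached it. In CD8 and CD4 T cells the highest other split, uninfected replicates 1 and 2 with 6-week replicate 2 against the rest, called several times the real count. It may follow a structure of the samples other than infection, and no table tests what that split reflects.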

How the results depend on the processing

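The alternatives with uninfected replicate 3 as the control alone, with T9 counted as CD4 T cells and with CD8 T cells without T8 were chosen only after the data were seen. Of the values for named genes under alternatives, 2456 kept their direction and side of the threshold, 270 lost the call and 94 gained one. Another 129, not called in the main fit, changed direction. For lists only the 132 calls of the main fit were followed, and of their values 1161 kept both, 263 lost the call and 28 reversed. Of the class shares 932 kept both, 72 lost the call, 25 gained one, 50 without a call changed direction and 1 with a call reversed. Named genes and class shares were also followed where the main fit had no call, so a kept value can be one that stayed uncalled. The 72 lost share calls came from the 9, 6 and 3 shares called at 6 weeks, at 16 weeks and between the times. Of the counts 191 stayed within 1.5 times the reported one and 155 did not. Of the differences in percentages of cells with a UMI, 50 stayed within 1 SD of the reported one and 22 moved further. Counts are given as 6 weeks over uninfected, 16 weeks over uninfected and 16 over 6 weeks, and where no construction is named the cause was not tested.

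By DESeq2 the counts were 57, 190 and 33 in CD8 T cells, 75, 164 and 19 in CD4 T cells, 428, 28 and 43 in Kupffer cells, 39, 13 and 37 in monocytes or macrophages, 285, 79 and 80 in endothelial cells, and 7, 5 and 13 in stellate cells. Of the reported genes, DESeq2 also called 111 of 124 in CD8 T cells at 16 weeks and all 37 in CD4 T cells and 21 in endothelial cells. With no filter on low counts, where more genes were tested, they were 267, 673 and 333 in CD8 T cells, 450, 717 and 280 in CD4 T cells, 890, 276 and 347 in Kupffer cells, 351, 152 and 72 in endothelial cells, 259, 138 and 174 in stellate cells, and 5 in monocytes or macrophages at 6 weeks.

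Replicate numbers recur across the groups, and the labels do not say what they stand for. Over whole libraries, centred within groups, same-number libraries correlated over genes at -0.03, -0.15 and -0.22 (uninfected with 6 weeks). The values were -0.32 and 0.03 (uninfected with 16 weeks) and 0.12 and 0.09 (6 with 16 weeks). In endothelial cells the correlations ran from -0.35 to 0.34 for same-number libraries and from -0.45 to 0.45 for others. In monocytes or macrophages they ran from -0.28 to 0.29 and from -0.34 to 0.40. Centring leaves the 16-week libraries as mirror images of each other, so these correlations cannot settle whether equal numbers pair the samples. With the replicate block the counts were 25 in CD8 T cells at 6 weeks and 12 between the times, 45, 176 (98 higher, 78 lower) and 0 in CD4 T cells, 2 in Kupffer cells at 6 weeks, 266 (97 higher, 169 lower), 222 and 2 in endothelial cells, and 3 class shares at 6 weeks, all higher.

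With doublets kept, the count was 0 in CD8 T cells at 6 weeks, 0, 0 and 0 in CD4 T cells, and 1 in Kupffer cells at 16 weeks. With stricter cells it was 0 in CD4 T cells at 6 weeks and between the times, and 4 in CD8 T cells between the times. At double resolution it was 7 in CD8 T cells at 6 weeks, 8 between the times, and 1 in CD4 T cells between the times, and class shares gave 2, 3 and 0. The smaller denominator also took hepatocytes, erythroid cells, megakaryocytes or platelets and unnamed clusters out of the tested shares, so their calls could not recur. That setting thereby left out every share called between the times. Of the shares that remained, 3 passed at 6 weeks and 0 between the times, and no call among them was lost. With TMM across classes 6 shares passed between the times. With an estimated correlation 3 of the 132 list calls held. Without T8, 34 genes passed in CD8 T cells at 16 weeks and 25 between the times. With T9 counted as CD4 T cells, 264, 72 and 17 passed.

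With uninfected replicate 3 as the control alone, assumed to vary like the other groups, 1, 66 and 28 genes passed in CD8 T cells, 0 in CD4 T cells at 16 weeks and 24 between the times, 0 in endothelial cells at 6 weeks and 2 between the times, 3, 3 and 1 in stellate cells, and 3 and 2 class shares at 6 and 16 weeks. Reversed there were the medians of MHC class II genes in endothelial cells (0.70 at 6 weeks, 0.69 at 16 weeks), and of stress genes at 6 weeks in CD8 T cells (-0.19), endothelial cells (-0.35) and monocytes or macrophages (-0.16). Only the direction of the test reversed, with the median keeping its sign, for stress genes in stellate cells at 16 weeks (0.027). The same held at 16 weeks for hepatocyte RNA in monocytes or macrophages (-0.030) and interferon genes in CD8 T cells (-0.035). The medians of hepatocyte RNA at 16 weeks reversed in CD8 T cells (0.39) and endothelial cells (0.82). Those of interferon genes at 6 weeks reversed in CD8 T cells (0.13) and monocytes or macrophages (0.42). Scar-associated genes in monocytes or macrophages at 16 weeks (0.65) and the hepatocyte share at 16 weeks (0.46) reversed too.

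Leaving out each library in turn, where a lone 16-week library is assumed to vary like the other groups, gave these ranges. CD8 T cells: 0 to 46 genes at 6 weeks, 24 to 199 at 16 weeks and 0 to 51 between the times. CD4 T cells: 0 to 94, 0 to 180 and 0 to 30. Kupffer cells: 0 to 1925, 0 to 5 and 0 to 10. Monocytes or macrophages: 0 to 4, 0 to 178 and 0 to 1. Endothelial cells: 0 to 288, 0 to 221 and 0 to 4. Stellate cells: 0 to 1 at 6 weeks and 0 to 1 at 16 weeks. Class shares: 2 to 9, 3 to 10 and 2 to 8. The highest value came without uninfected replicate 3 in each range whose highest was 30 or more, except for CD8 T cells at 16 weeks, where it came without 16-week replicate 2. The genes called in CD8 T cells at 16 weeks without 16-week replicate 1 included 18 of the 124, and those without 16-week replicate 2 included 84.

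Some lists reversed, by the median or by the direction of the test, when a library was left out. Between 16 and 6 weeks, stress genes ran from -0.38 without 16-week replicate 1 to 1.68 without 16-week replicate 2 in CD8 T cells, from -0.26 to 0.92 in CD4 T cells, from -0.44 to 2.16 in Kupffer cells and from -0.45 to 1.22 in endothelial cells. At 16 weeks over uninfected they ran from -0.26 to 2.56 in Kupffer cells and from -0.0089 to 1.98 in endothelial cells. Residency genes in CD8 T cells between the times ran from 0.033 without 16-week replicate 1 to 0.82, with only the direction of the test reversed. Other ranges were -3.22 to 0.79 (erythroid RNA, CD8 T cells, 6 weeks), -3.36 to 6.68 (erythroid RNA, stellate cells, between the times), -0.32 to 1.17 (inflammatory genes, Kupffer cells, between the times) and -2.35 to 0.51 (proliferation, Kupffer cells, 16 weeks). Between the times, interferon genes ran from -0.72 to -0.13 in Kupffer cells, where again only the direction of the test reversed. They ran from -0.90 to 0.034 in monocytes or macrophages between the times, and from -0.12 to 0.37 in endothelial cells at 6 weeks.

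Stellate cells rested on 23 to 105 cells per library, and of simulated 4-fold changes 65% were recovered there at 6 weeks and 39% at 16 weeks. That class may also hold mesothelial cells, which were named apart from it only at double resolution. In CD8 T cells, with 102 to 821 cells per library, 83% and 88% were recovered.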

Other observations

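At 6 weeks cluster T9 and ILC2 took larger shares of cells, and Il33 rose in endothelial cells by 1.41 on the log2 scale (SE 0.20, adjusted p = 0.0382, edgeR). No list across classes was fixed for these, and no test linked them to each other.

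No hypothesis beyond those weighed with the tests above was tested.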
